A study of Mus musculus with 16 samples.

How the data were processed

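RNA was measured in 16 libraries from 8 mouse embryos taken at embryonic day 15.5, with 1 atrial and 1 ventricular library per embryo. Per the labels' protocols, hearts were dissected, the outflow tract was removed and atria and ventricles were separated and frozen, and polyadenylated RNA from 20 ng of total RNA was made into NEBNext Ultra libraries and read as single reads of 60 bases. Per the submitters' processing notes, reads were trimmed with cutadapt and quantified with RSEM 1.3.1 on the mouse build GRCm38. The deposited values are counts normalized for library size (CPM) of 16118 genes. The normalization method, the gene filter, the annotation release and the use of strand are not given in the sources used here.

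Each deposited CPM value equals a whole number of reads plus 0.5, multiplied by 1 step per library, and 100% of the values gave a whole read number within a tolerance of 0.001. The step was taken from the lowest value of each library, and these recovered reads served for depths and for the tests on counts. The library size behind the CPM is larger than the sum of the listed reads, so the CPM of the listed genes do not add up to the nominal total. Recovered reads ranged from 7.88 to 23.0 megareads per library. A count of 3 reads, taken as the floor of detection, corresponded to 0.110 to 0.312 CPM. Between replicates of a group the reads varied by 6.47 to 25.7 times the variance that counting alone would give (chi-square per degree of freedom over 24 pairs). Averaged over genes, counting error is therefore the smaller part of the spread. This average leaves out genes with the fewest reads and need not hold for genes with few reads.

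The fits used log2 of CPM with a pseudocount of 1 and the 13950 genes with a mean of at least 1 CPM over all 16 libraries. The planned minimum was 10 normalized counts, or 1 where the values are CPM, and the latter applied. Fold changes on this scale understate the change of genes near the pseudocount. Control and double knockout (dKO) libraries were compared in atria and in ventricles separately with limma 3.58.1 (R 4.3.3), using its moderated test with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05 with no fold minimum. The chamber difference in control embryos, and the difference of the dKO effect between chambers, were fitted to all 16 libraries with embryo as a block. The block rests on the same animal giving an atrium and a ventricle, and the fitted consensus correlation of both chambers of an embryo was 0.108. Genotypes were not paired, since replicate numbers mark no shared litter in the labels. On simulated data with 200 changed genes the atrial test recovered 79% of genes changed by a log2 fold of 1 and 45% of those changed by 0.5, with 6.77% false calls. The ventricular test recovered 79% and 47% with 5.97% false calls, and the test of the difference between chambers recovered 68% and 27% with 7.77% false calls.

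Before the data were examined, 45 gene lists were written, along with the tests, most alternatives and the rule for the genes the text names. Of the lists, 39 had at least 5 tested members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the 39 lists. The same lists were tested with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and does not compare a list with other genes. Meis1 and Meis2 were compared with a two-sided exact permutation test over 70 arrangements of 4 against 4 libraries, whose smallest p is 0.0286.

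The named genes were, for each dKO comparison, Meis1 and Meis2, the 10 largest rises and the 10 largest falls among called genes whose groups did not overlap and that have an ordinary symbol, and up to 3 members of each list with the smallest adjusted p under 0.05. For a described list with no called member, the 2 members with the highest mean level were named. The difference of the dKO effect between chambers and the control chamber comparison gave the 5 largest genes each way, and 8 genes with the smallest larger adjusted p stood for those called the same way in both chambers. Of the genes this rule gave, 2 are not reported here. Genes differing between title numbers are outside this rule and were chosen after their values were seen. Of 133 genes compared with the annotation, 19 have exons that overlap another listed gene, 18 of them on the opposite strand. Without a stated use of strand their values are uncertain. These are Angpt1, Atp5a1, Cd34, Eng, Fabp3, Fbn1, Gja5, Hmga1, Kcnq1, Mb, Mef2d, Mybphl, Myh7, Myl3, Myom1, Nppa, Ryr3, Slc1a1 and, on the same strand, Pam. Ces1d, the globins, Myh6 with Myh7, and Hmga1 have close paralogs or pseudogenes and are uncertain for that reason. IDs of 16096 of the 16118 genes matched GENCODE M21, which gave the GRCm38 coordinates.

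Alternatives planned beforehand were a pseudocount of 0.5 or 5, no filter, a mean of at least 50 CPM, re-centred libraries, quantile normalization, a robust variance prior, a fold of at least 2, all 16 libraries in 1 fit with and without an embryo block, the title number as a covariate, the title number shared by 2 embryos of each genotype alone, no genes on the sex chromosomes, an estimated correlation or fry for the lists, and leaving out each library or embryo in turn. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, log2 of the deposited values without a further pseudocount, a mean of at least 5 CPM, the mean level of 5 lists of cells other than myocytes as a covariate, and ventricular reads thinned at random to the shallowest library. Chance was weighed by refitting every one of the 35 splits of the 8 embryos into 4 and 4.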

Results

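Gene expression was measured in atria and ventricles of 8 mouse embryos at E15.5. The embryos were 4 with a deletion of Meis1 and Meis2, a pair of TALE homeobox transcription factors, driven by a Cre recombinase under the cardiomyocyte promoter of alpha-myosin heavy chain (dKO), and 4 controls, which the series design calls littermates. The protocol names 4 litters. The numbers in the titles do not match 1 control and 1 dKO embryo per litter. A first number covers 1 dKO embryo and no control, another 2 of each genotype and the third 2 control and 1 dKO embryo. The series design speaks of a deletion that is constitutive or inducible, and which of these applies to the embryos here was not settled from the labels. By the labels all 8 carried floxed alleles of both genes and only the dKO embryos carried Cre, so the presence of Cre goes with the deletion in every comparison. The series design names the comparison of dKO with control tissue in each chamber. Recovered reads, in megareads (M), averaged 16.9 ± 2.54 M in dKO atria, 17.5 ± 1.98 M in control atria, 12.3 ± 3.0 M in dKO ventricles and 18.4 ± 3.18 M in control ventricles (SD, n = 4 each). Every dKO ventricle library was shallower than every control ventricle library (7.88 to 14.3 M against 15.6 to 23.0 M, exact permutation p = 0.0286). Chamber was the main axis of the data, and the first principal component held 57.0% of the variance.

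The targeted genes were lower in dKO tissue in 1 chamber each. In atria, Meis1 (ENSMUSG00000020160, chromosome 11, 18879817 to 19018985) measured 26.1 ± 3.19 CPM in dKO and 40.4 ± 2.61 CPM in control libraries (SD, n = 4), 64.5% of the control level, a log2 difference of -0.62 (two-sided exact permutation p = 0.0286, the smallest this design allows). In ventricles Meis1 measured 40.9 ± 2.41 CPM in dKO and 41.5 ± 3.96 CPM in control libraries, 98.5% of control (exact permutation p = 0.829). Meis2 (ENSMUSG00000027210, chromosome 2, 115863064 to 116065839) showed the opposite distribution. It measured 23.4 ± 2.85 CPM in dKO and 39.2 ± 3.46 CPM in control ventricles, 59.6% of control and a log2 difference of -0.73 (exact permutation p = 0.0286), against 26.5 ± 1.90 and 25.4 ± 2.04 CPM in atria, 105% of control (exact permutation p = 0.457). The dKO effect differed between chambers for Meis1 (log2 0.60 in ventricles minus atria, limma adjusted p = 0.0146) and for Meis2 (-0.79, adjusted p = 0.00269). The Meis1 difference between chambers lost its call without dKO embryo 3, control embryo 3 or control embryo 4 (log2 0.53 to 0.58, adjusted p 0.0582 to 0.0639). The values count reads over the whole gene, and the position of the floxed exons was not used here, so transcripts that lack an exon would still be counted.

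**Figure D1:**
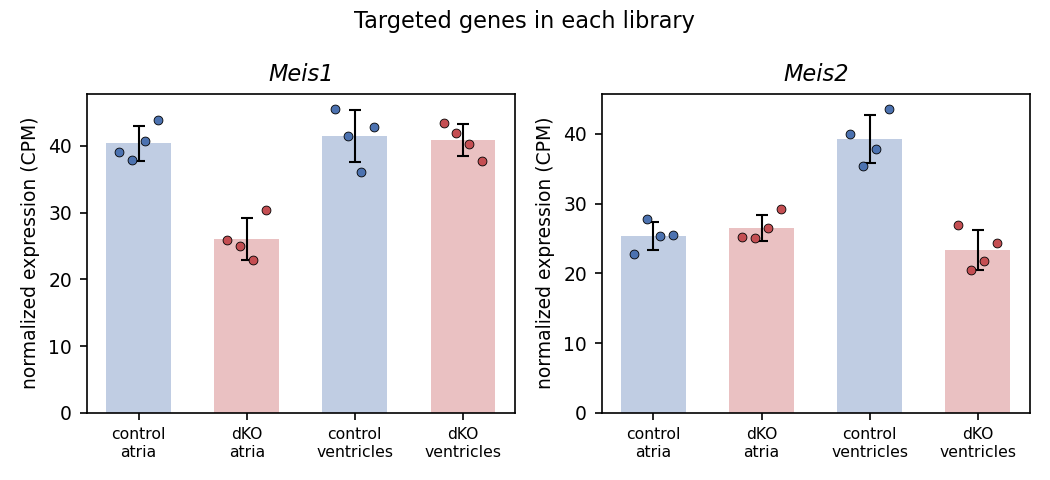
Normalized expression of Meis1 and Meis2 (y axis, CPM) in control and dKO atria and ventricles (x axis). Points are single libraries, bars are means and error lines are SD of 4 libraries, and the dKO libraries lie at 22.9 to 30.5 CPM for Meis1 in atria against 37.9 to 43.9 CPM in controls.

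Genes that differed between ventricles and atria of control embryos included known markers of each chamber. Myl2, the ventricular myosin regulatory light chain, was higher in ventricles by a log2 fold of 7.48, and so were Irx4, a ventricular homeobox factor (5.95), Mb, myoglobin (5.45), Kcne1, a potassium channel subunit (4.71), and Myh7, the beta-myosin heavy chain (4.50). Sln, the calcium pump inhibitor sarcolipin, was lower in ventricles by -5.91, and so were Fgf12 (-5.62), Mybphl, an atrial myosin-binding protein (-5.59), Vsnl1 (-5.20) and Slc17a7 (-4.72). The order of these folds depends on the pseudocount, and over the alternatives Irx4 measured 4.01 to 8.29, Myl2 7.23 to 7.79, Fgf12 -7.29 to -3.84 and Sln -6.37 to -4.94. In the limma fit with embryo as a block, 6401 of 13950 genes differed, 3589 higher and 2812 lower in ventricles. The balance of directions turned with the scaling, with 3107 higher and 3163 lower after re-centring, 3069 and 3203 by edgeR and 2817 and 2883 by DESeq2. At a fold of at least 2, 321 genes were higher in ventricles and 579 in atria.

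In dKO atria Ryr3 (ENSMUSG00000057378), an intracellular calcium release channel, fell from 72.4 ± 4.86 to 9.80 ± 2.12 CPM (SD, n = 4; log2 -2.78 ± 0.13 SE, adjusted p = 1.24e-06). Gsg1l, an auxiliary subunit of AMPA receptors, fell from 54.5 to 8.32 CPM, Dsc2, the desmosomal cadherin desmocollin 2, from 42.2 to 8.89 CPM, and Lrrc10, a cardiomyocyte leucine-rich repeat protein, from 25.1 to 4.96 CPM. Dpp6, an auxiliary subunit of Kv4 potassium channels, fell by 2.47 on the log2 scale, the diacylglycerol kinase Dgkk by 2.37, the ephrin Efnb3 by 2.09 and the cholecystokinin receptor Cckar by 1.97. Uts2b, encoding a urotensin-like vasoactive peptide, fell from 14.6 ± 3.05 to 0.820 ± 0.607 CPM, and Ap3b2, an adaptor subunit of vesicle transport, from 13.4 to 1.3 CPM. Among the rises, Sfrp5, a secreted Wnt antagonist, increased from 6.47 ± 1.78 to 50.7 ± 4.11 CPM (log2 2.82 ± 0.15 SE, adjusted p = 2.2e-06). The cadherin-related Cdhr1 rose by 2.77, the GTPase activating protein Arhgap36 by 2.76, the carboxylesterase Ces1d by 1.91, the leukotriene-forming lipoxygenase Alox5 by 1.79, the scavenger receptor protein Ssc5d by 1.76, the chaperone clusterin (Clu) by 1.67, the transporter Slco5a1 by 1.67, the GABA-forming enzyme Gad1 by 1.65 and the LIM protein Csrp2 by 1.51. Limma called 1042 of 13950 genes, 563 higher and 479 lower in dKO atria, edgeR called 1031 and DESeq2 1552. With the mean level of 5 lists of cells other than myocytes as a covariate (the non-myocyte covariate), 163 genes were called. This level separates the genotypes completely (5.43 to 5.65 in dKO and 5.23 to 5.34 in control atria), so a call lost under it points to no source. Lost calls were those of Meis1 (log2 -0.65), Cdhr1 (3.0), Arhgap36 (2.62), Ces1d (1.83), Alox5 (1.47) and Gad1 (1.72; adjusted p 0.0531 to 0.265). At low levels the folds depend on the pseudocount and the tool, and over the alternatives those of Dpp6 measured -3.62 to -1.28, Cckar -3.60 to -0.83, Ces1d 1.04 to 2.54, Alox5 0.86 to 2.64, Slco5a1 0.93 to 2.14 and Gad1 0.75 to 2.51.

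**Figure D2:**
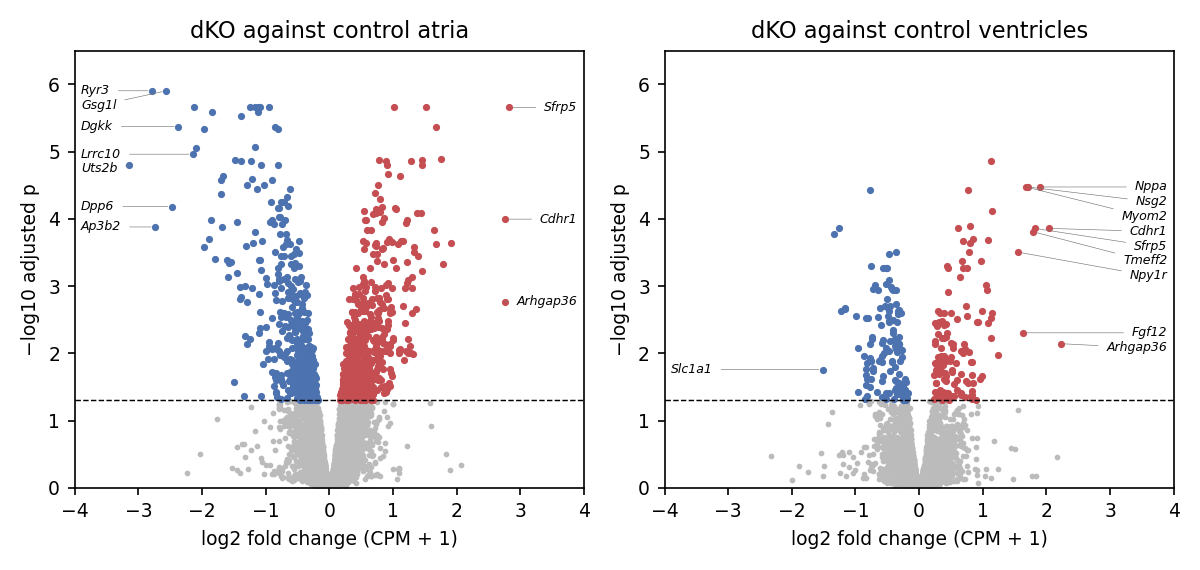
Log2 fold change of each tested gene (x axis, dKO minus control, log2 of CPM plus 1) against minus log10 of the limma adjusted p (y axis) in atria and ventricles. Red points rose and blue points fell at an adjusted p under 0.05 (dashed line), grey points were not called, and the named genes are those with the largest changes, such as Ryr3 at -2.78 in atria and Nppa at 1.90 in ventricles.

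Most members of the lists of myocyte identity, excitation and contraction were not called in dKO atria. Of those called in the ventricular, potassium channel, calcium and sarcomere lists more fell than rose. Of 14 ventricular myocyte markers, 6 fell and none rose (camera adjusted p = 0.000122, adjusted p = 0.529 with an estimated correlation). Examples are Gja1, the gap junction protein connexin 43 (log2 -1.39), the transcriptional regulator Cited1 (-1.85) and Lrrc10 (-2.14). Of 22 potassium channel genes 4 fell and 1 rose (camera adjusted p = 0.0490, adjusted p = 0.529 with an estimated correlation), with falls of Kcnq1 (-1.10) and of Abcc9 (-1.12) and Abcc8 (-0.51), the sulfonylurea receptors of ATP-sensitive channels, and a rise of Kcna4 (0.42). Of 22 calcium handling genes 4 fell and 1 rose (camera adjusted p = 0.0267, adjusted p = 0.529 with an estimated correlation), with falls of the L-type channel Cacna1c (-0.72) and the kinase Camk2a (-0.61) and a rise of Sln (0.69). Of 28 sarcomere genes 4 fell and 2 rose (camera adjusted p = 0.0249, adjusted p = 0.668 with an estimated correlation), with falls of Myl3, the ventricular myosin essential light chain (-1.58), of Myom1 in the M-band (-0.47) and of Ldb3 in the Z-disc (-0.33). Beside these falls, the natriuretic peptide genes Nppa (0.63) and Nppb (0.96) rose. Hspb7, a small heat shock protein of myocytes, fell (-0.87), Cpne5 of the trabecular and compact layer list fell (-1.48), and the conduction and pacemaker list members Etv1 (-0.71) and Cacna2d2 (-0.80) fell. Of 18 atrial myocyte markers 3 rose and 2 fell (camera adjusted p = 0.619), with rises of Fgf12 (0.83) and Sln and a fall of Dkk3 (-0.78). Adjusted over the list alone, 7 ventricular markers fell and 1 rose, 7 potassium channel genes fell and 3 rose, 6 calcium handling genes fell and 2 rose, and 6 sarcomere genes fell and 2 rose. Ventricle-enriched genes as a class showed no such fall in dKO atria. Of 321 genes higher in control ventricles by a fold of at least 2, 37 rose and 28 fell (median log2 0.068). In dKO ventricles 6 of them rose and 32 fell (median -0.11). The same control libraries chose these genes and were compared with dKO, which favours a rise in atria and a fall in ventricles. Of the 35 splits of the 8 embryos into 4 and 4, 11 called as many lists in atria as the 12 of the real split. The mean levels of fibroblast, epicardial and macrophage markers differed in the same dKO atria by a log2 of 0.34, 0.25 and 0.39 (exact permutation p = 0.0571, 0.0286 and 0.0857). Library dKO atrium 1 lay inside the control range for fibroblast (6.72 against 6.62 to 6.91) and macrophage markers (2.93 against 2.84 to 3.02). The same held for smooth muscle markers (5.50 against 5.41 to 5.55). Its epicardial (5.37 against 4.87 to 5.09) and endothelial markers (6.62 against 6.29 to 6.38) lay above every control. Its ventricular markers (4.81) lay below every control. The call of the potassium channel list was lost with the title number as a covariate (adjusted p = 0.0608), with a pseudocount of 5 (0.0530), at a mean of at least 5 CPM (0.0504) and without dKO atrium 1 or 4 or control atrium 3 or 4 (0.0511 to 0.0694). That of the calcium list was lost at a mean of at least 50 CPM (0.107) and without dKO atrium 4 (adjusted p = 0.142). That of the sarcomere list was lost with quantile normalization (0.0533), at a mean of at least 50 CPM (0.107) and without control atrium 4 (adjusted p = 0.185). Nppa lost its call with quantile normalization (log2 0.41), with no filter, within the 4 embryos of the shared title number (0.49) and without dKO atrium 3 or control atrium 2, 3 or 4 (0.55 to 0.64), and Nppb with a robust variance prior (0.96) and without dKO atrium 2 or 3 or control atrium 2 or 3 (0.82 to 0.92). With the non-myocyte covariate the lost calls were those of Nppa (0.97), Nppb (1.12), Cited1 (-1.34), Kcnq1 (-1.24), Cacna1c (-0.57), Camk2a (-0.49), Myl3 (-0.42), Myom1 (-0.17), Ldb3 (-0.25), Hspb7 (-0.97), Etv1 (-0.14), Cacna2d2 (-1.02) and Dkk3 (-0.53; adjusted p 0.0508 to 0.802), and Abcc8 turned to 0.033.

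**Figure D3:**
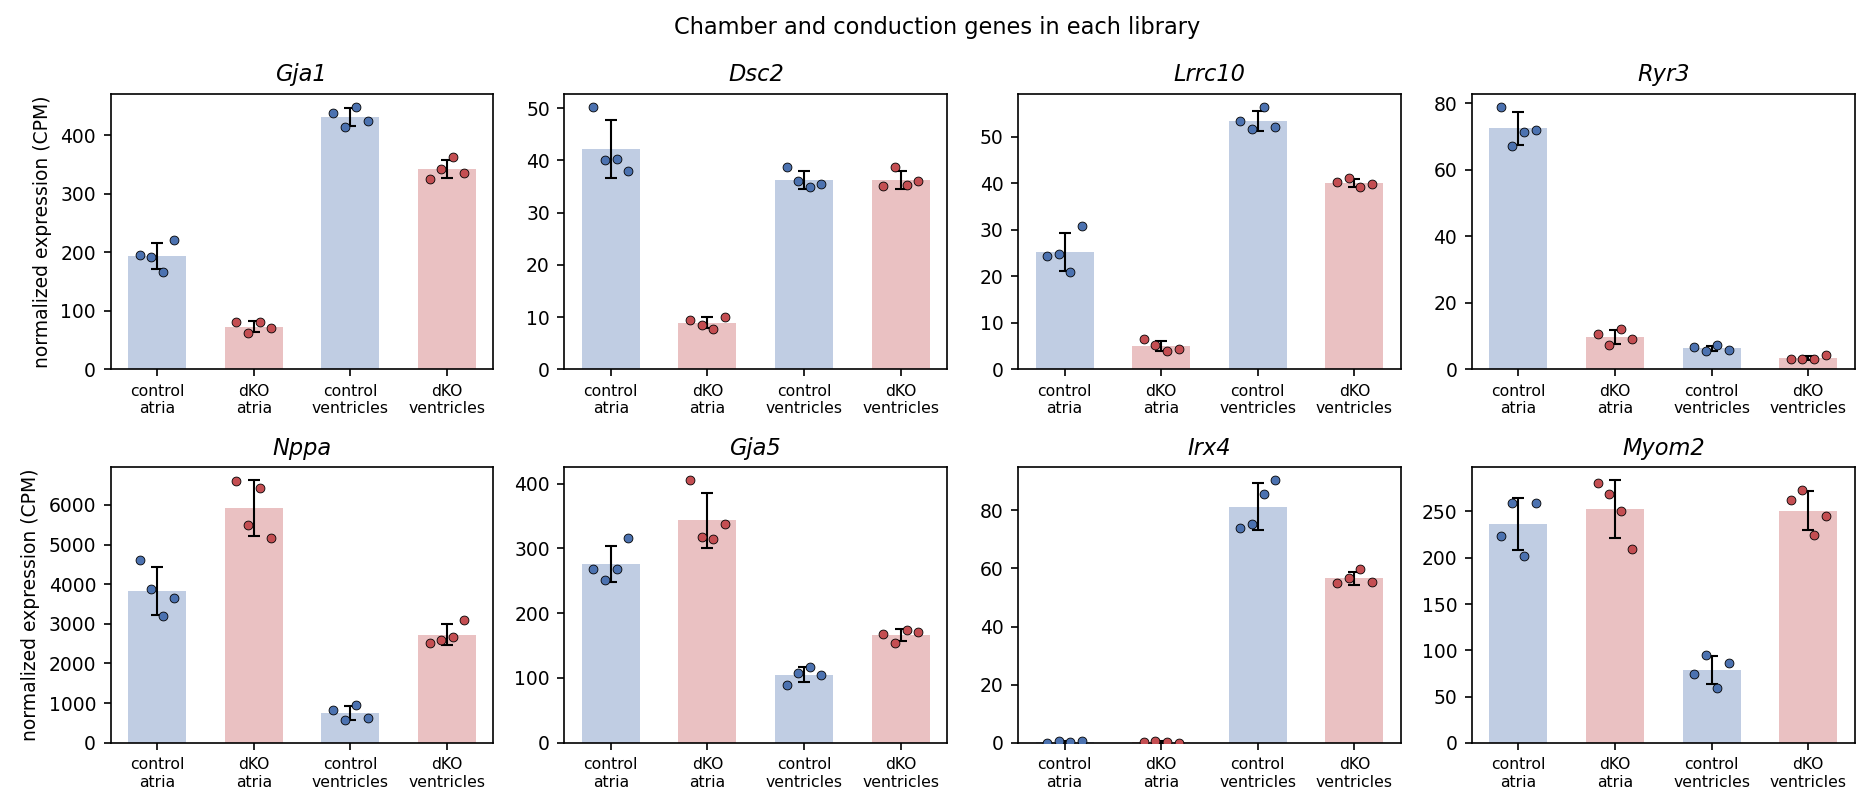
Normalized expression (y axis, CPM) of 8 genes of chamber identity, cell contact and conduction in control and dKO atria and ventricles (x axis). Points are single libraries, bars are means and error lines are SD of 4 libraries, and Dsc2 averages 8.89 CPM in dKO atria against 36.3 CPM in dKO ventricles.

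The fatty acid oxidation and nuclear oxidative phosphorylation lists were lower in dKO atria by camera at the preset correlation, with few single genes past the threshold. Of 23 fatty acid oxidation genes 3 fell and none rose, namely the fatty acid binding protein Fabp3 (log2 -0.65), Eci1 (-0.43) and Acads (-0.32), enzymes of beta-oxidation (camera adjusted p = 0.000122, adjusted p = 0.529 with an estimated correlation). Of 34 nuclear oxidative phosphorylation genes none was called by limma (camera adjusted p = 5.2e-05, adjusted p = 0.584 with an estimated correlation), and the ATP synthase subunits Atp5b and Atp5a1, the highest by level, measured -0.12 and -0.15. Of 20 glycolysis genes 4 fell, among them the glucose transporter Slc2a1 (-0.71), the hexokinase Hk1 (-0.56) and the aldolase Aldoc (-0.45), and the list was not called (camera adjusted p = 0.0519). Nor were the 13 mitochondrially encoded genes, whose mean level differed by a log2 of -0.07 (camera adjusted p = 0.186, exact permutation p = 0.2). Adjusted over the list alone, 11 fatty acid oxidation genes fell and 2 rose, 0 oxidative phosphorylation genes were called and 4 glycolysis genes fell. The mean level of fibroblast markers differed by a log2 of 0.34 between these groups (exact permutation p = 0.0571), with dKO atrium 1 inside the control range. For epicardial and endothelial markers that library lay above every control. Aldoc lost its call with no filter (adjusted p = 0.0504), within the 4 embryos of the shared title number (0.117) and without dKO atrium 2 or control atrium 1, 2 or 4 (log2 -0.44 to -0.36). With the non-myocyte covariate Fabp3 (-0.86), Eci1 (-0.24), Acads (-0.15), Slc2a1 (-0.79) and Aldoc (-0.32) lost their calls (adjusted p 0.0905 to 0.701).

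The extracellular matrix, fibroblast, epicardial, coronary vessel, macrophage and atrioventricular canal lists were higher in dKO atria by camera at the preset correlation. Of 24 extracellular matrix genes 5 rose and none fell (camera adjusted p = 7.0e-06, adjusted p = 0.529 with an estimated correlation), such as the matricellular protein Sparc (log2 0.40), fibrillin Fbn1 (0.37) and nidogen Nid1 (0.26). Of 13 fibroblast markers 2 rose, the proteoglycan decorin Dcn (0.47) and the transcription factor Tcf21 (0.44). Of 12 epicardial markers 2 rose, Tcf21, which is in both lists, and mesothelin Msln (0.59). Camera gave an adjusted p of 0.000124 for fibroblast and 0.00148 for epicardial markers, and an adjusted p of 0.529 for each with an estimated correlation. Of 9 coronary vessel markers 3 rose, the connexin Gja4 (0.48), the fatty acid binding protein Fabp4 (0.60) and the ephrin Efnb2 (0.25), and of 14 macrophage markers 1 rose, the complement gene C1qb (0.63). Their camera adjusted p were 0.00482 and 0.000124, with an adjusted p of 0.529 for each with an estimated correlation. Of 12 atrioventricular canal genes Tbx2, a transcriptional repressor (0.88), and Bmp2 (0.73) rose and the peptide gene Adm fell (-0.44; camera adjusted p = 0.0231, adjusted p = 0.529 with an estimated correlation). Smooth muscle and pericyte markers moved both ways, with rises of the proteoglycan Cspg4 (1.21) and smooth muscle actin Acta2 (0.90) and a fall of Abcc9 among 4 rises and 1 fall of 10 (camera adjusted p = 0.0555). So did endothelial markers, with rises of Cd34 (0.52) and endoglin Eng (0.37) and a fall of the VEGF receptor Kdr (-0.23) among 17 (camera adjusted p = 0.0519). The 10 valve mesenchyme and 8 neural and glial markers held no called gene, and their mean levels differed by a log2 of 0.16 (exact permutation p = 0.486) and -0.26 (p = 0.686). Adjusted over the list alone, 14 matrix genes, 8 fibroblast, 3 epicardial, 3 coronary and 2 macrophage markers rose, 3 atrioventricular canal genes rose and 1 fell, 6 smooth muscle markers rose and 2 fell, and 5 endothelial markers rose and 1 fell. In Eng, Fabp4 and Tcf21 the groups overlapped. Of the fits that left out 1 library, Eng lost its call in all but the one without dKO atrium 4 (log2 0.31 to 0.40), and Fabp4 in all but that without dKO atrium 1 (0.48 to 0.63). Kdr lost it in all but those without dKO atrium 2 or 4 (-0.24 to -0.21), Msln in all but those without dKO atrium 4 or control atrium 1 (0.45 to 0.63), and Tcf21 in all but those without dKO atrium 1 or control atrium 3 (0.37 to 0.45). Without control atrium 4, Dcn (0.42), Fbn1, C1qb, Nid1, Efnb2 and Adm lost theirs. So did Fbn1 without control atrium 2 (0.33 to 0.35 in both) and C1qb without dKO atrium 2 or 3 (0.57 to 0.60). The same held for Nid1 without dKO atrium 2 or 3 or control atrium 2 (0.21 to 0.27), Efnb2 without dKO atrium 2 or 3 or control atrium 3 (0.22 to 0.25) and Adm without dKO atrium 3 or control atrium 3 (-0.43 to -0.40). The canal list lost its call without dKO atrium 4 (adjusted p = 0.0694). Sparc lost its call with quantile normalization (adjusted p = 0.0643), Eng, Fabp4, Msln and Tcf21 with no filter (0.0552 to 0.0695), Fabp4 and Msln with a robust variance prior (0.0543 and 0.0576), and Adm and Msln with all 16 libraries in 1 fit (0.0548 to 0.102). With that fit and a random embryo block Tcf21 did too. Within the 4 embryos of the shared title number Adm, Dcn, Efnb2 and Kdr lost theirs (0.0544 to 0.122). The non-myocyte covariate is the mean level of the fibroblast, epicardial, endothelial, macrophage and smooth muscle lists themselves. Under it Sparc (0.13), Fbn1 (0.10), Nid1 (0.20), Dcn (0.10), Msln (1.21), Gja4 (0.49), Efnb2 (0.09), Bmp2 (0.81), Adm (-0.72), Cspg4 (1.04), Acta2 (0.49), Cd34 (0.46), Eng (0.77) and Kdr (-0.31) lost their calls (adjusted p 0.0672 to 0.886), and C1qb, Fabp4, Tbx2 and Tcf21 turned negative.

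In dKO ventricles Nppa (ENSMUSG00000041616), encoding atrial natriuretic peptide, increased from 744 ± 182 to 2722 ± 264 CPM (SD, n = 4; log2 1.90 ± 0.14 SE, adjusted p = 3.36e-05). Myom2, an M-band protein, rose from 78.7 to 251 CPM (log2 1.68), and Xirp2, an actin-binding protein of the intercalated disc, from 3.47 to 9.86 CPM (1.23). Sfrp5 (1.82), Cdhr1 (2.03), Arhgap36 (2.23), the transmembrane protein Tmeff2 (1.79), the vesicle protein Nsg2 (1.71), the sodium channel modulator Fgf12 (1.63) and the neuropeptide Y receptor Npy1r (1.56) also rose. Dio2, the enzyme that activates thyroid hormone, fell from 9.24 ± 0.610 to 3.07 ± 0.489 CPM (log2 -1.34 ± 0.13 SE, adjusted p = 0.000168), and Angpt1, a ligand of the Tie2 receptor, from 21.7 to 8.54 CPM (-1.26). The glutamate transporter Slc1a1 fell by 1.51, the lipoxygenase Alox8 by 1.23, Togaram2 by 1.17, Dgkk by 0.99, the alpha-1D adrenergic receptor Adra1d by 0.96, Eprn by 0.96 and the receptor Megf10 by 0.86. Alox8 measured 0.156 CPM in dKO ventricles, at or near the floor of 3 reads, against 1.72 CPM in controls. Over the alternatives the folds measured -3.74 to -0.38 for Alox8, -2.07 to -0.45 for Togaram2, -2.24 to -0.80 for Slc1a1, -1.65 to -0.41 for Adra1d, -1.17 to -0.56 for Eprn, -1.14 to -0.45 for Megf10 and -1.60 to -0.82 for Dio2. Those of the rises measured 0.83 to 4.04 for Cdhr1, 1.303 to 3.011 for Arhgap36, 0.90 to 2.50 for Tmeff2, 0.90 to 2.30 for Nsg2, 0.67 to 2.95 for Fgf12, 0.72 to 2.36 for Npy1r, 1.21 to 2.11 for Sfrp5 and 0.78 to 1.54 for Xirp2. The chromatin protein Hmga1 fell from 72.2 ± 4.01 to 32.9 ± 11.4 CPM, with dKO ventricle 4 at 49.96 CPM and the other dKO ventricles at 25.9 to 27.9 CPM. The atrium of the same embryo stood apart as well, at 39.1 CPM against 13.1 to 13.3 CPM in the other dKO atria. It lay inside the range of control atria, 35.3 to 41.2 CPM. Limma called 279 of 13950 genes, 138 higher and 141 lower. By edgeR 259 were called, 145 higher and 114 lower, and by DESeq2 469, 249 higher and 220 lower. The balance of directions moved with the setting, with 159 higher and 121 lower after quantile normalization and 19 and 6 at a fold of at least 2. Within the 4 embryos that share the number carried by 2 control and 2 dKO titles, 79 genes were called, and Xirp2, Fgf12, Npy1r, Slc1a1, Alox8, Togaram2, Adra1d, Eprn and Megf10 lost their calls (adjusted p 0.0539 to 0.470). Megf10 also lost its call with reads thinned to the shallowest library (adjusted p = 0.0567). Arhgap36 and Hmga1 lost their calls in ventricles with a robust variance prior (adjusted p = 0.103 and 0.0528), Slc1a1 with a pseudocount of 5 (0.0554) and Fgf12 at a mean of at least 50 CPM (0.146). Adra1d lost its call with a pseudocount of 5 (0.0638), with no filter (0.0534), with the title number as a covariate (0.0562) and in every fit that left out 1 library but those without control ventricle 3 or 4 (log2 -0.997 to -0.749).

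In dKO ventricles the ventricular marker list was lower and the atrial marker list higher by camera at the preset correlation. Of 14 ventricular myocyte markers 5 fell and none rose (camera adjusted p = 1.8e-09, adjusted p = 0.242 with an estimated correlation), among them Irx4 (log2 -0.51), Lrrc10 (-0.40) and Gja1 (-0.33). Of 18 atrial myocyte markers 6 rose and 1 fell (camera adjusted p = 0.0117, adjusted p = 0.728 with an estimated correlation), with rises of Nppa and of Pam, a peptide-amidating enzyme (0.78), and a fall of Angpt1. Of 16 conduction genes 3 rose and 2 fell (camera adjusted p = 0.0134, adjusted p = 0.594 with an estimated correlation), with a rise of connexin 40, Gja5 (0.67), and falls of Gja1 and of Id2, an inhibitor of helix-loop-helix factors (-0.42). Among other heart genes, the transcription factors Tbx2 (0.70) and Tbx20 (0.35), the stress gene Ankrd1 (0.75), the atrial myosin light chain Myl4 (0.46), the potassium channel genes Kcna4 (0.51) and Kcnj5 (0.35), the calcium channel Cacna1h (0.30) and the G-protein regulator Rgs6 (0.41) rose. Irx2 (-0.59), the calcineurin regulator Rcan1 (-0.45), Kcnq1 (-0.47) and Cacna1c (-0.28) fell. Adjusted over the list alone, 9 ventricular markers fell, 6 atrial markers rose and 4 fell, and 5 conduction genes rose and 2 fell. Of the 35 splits of the embryos, 13 called as many lists in ventricles as the 9 of the real split. The call of the atrial list was lost without control ventricle 4 (adjusted p = 0.0632) and that of the conduction list without control ventricle 1 (adjusted p = 0.0625) and at a mean of at least 5 CPM (0.132). Of the fits that left out 1 library, Cacna1c lost its call in all but those without dKO ventricle 1 or control ventricle 2 (log2 -0.29 to -0.23), Rgs6 in all but that without dKO ventricle 2 (0.37 to 0.45), and Id2 without control ventricle 3 or 4 (-0.40 to -0.39). Cacna1c also lost its call with no filter, quantile normalization and edgeR (adjusted p 0.0507 to 0.0878), and Rgs6 with no filter, the title number as a covariate and thinned reads (0.0725 to 0.173). With all 16 libraries in 1 fit of 4 groups, Irx4, Irx2, Lrrc10, Cacna1c and Cacna1h lost theirs (adjusted p 0.0609 to 0.129). Within the 4 embryos of the shared title number so did these 5, Gja1, Id2, Tbx2, Tbx20, Kcna4, Kcnj5, Kcnq1, Rgs6 and Rcan1 (adjusted p 0.0632 to 0.525).

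The glycolysis, hypoxia, fatty acid oxidation, nuclear oxidative phosphorylation and cell cycle lists were lower in dKO ventricles by camera at the preset correlation, with few called members. Of 20 glycolysis genes and of 18 hypoxia response genes 1 fell, in both cases Slc2a1 (log2 -0.57; camera adjusted p = 0.000501 and 0.00485, and for both lists an adjusted p = 0.728 with an estimated correlation). Of 23 fatty acid oxidation genes none was called, Acadl and Hadha measuring -0.11 and -0.11 (camera adjusted p = 0.000609, adjusted p = 0.728 with an estimated correlation). Of 34 oxidative phosphorylation genes none was called, Atp5b and Atp5a1 measuring -0.09 and -0.09 (camera adjusted p = 0.0435, adjusted p = 0.861 with an estimated correlation). Of 31 cell cycle genes 1 fell, the centromere histone Cenpa (-0.20; camera adjusted p = 0.0104, adjusted p = 0.728 with an estimated correlation). Of 9 erythroid markers none was called, although the list was higher (camera adjusted p = 0.000644, adjusted p = 0.728 with an estimated correlation), with the globins Hbb-bs and Hba-a2 at 0.34 and 0.31. Adjusted over the list alone, 4 glycolysis genes, 2 hypoxia genes and 1 cell cycle gene fell and 0 genes of the other lists were called. Exact permutation p of the list means were 0.0286 for glycolysis, 0.0857 for hypoxia, 0.143 for fatty acid oxidation and 0.457 for oxidative phosphorylation. They were 0.257 for the cell cycle list and 0.171 for erythroid markers. By fry the adjusted p of these lists ran from 0.278 to 0.610. The cell cycle list lost its call with the title number as a covariate (adjusted p = 0.180), with quantile normalization (0.0555), at a mean of at least 50 CPM (0.0698) and without dKO ventricle 1 or 4 or control ventricle 4 (0.0643 to 0.181). The hypoxia list lost it at a mean of at least 50 CPM (0.0743) and without dKO ventricle 4 (adjusted p = 0.0595). The oxidative phosphorylation list kept its call in 7 of 17 alternatives with the preset correlation. It lost it with the title number as a covariate (adjusted p = 0.182), re-centred libraries (0.0688), quantile normalization (0.408), at a mean of at least 5 CPM (0.0799) or 50 CPM (0.177), and without dKO ventricle 1, 3 or 4 or control ventricle 2 or 4 (adjusted p 0.228 to 0.430). Slc2a1 lost its call within the 4 embryos of the shared title number (adjusted p = 0.181). Cenpa lost its call in 20 of 26 alternatives, among them every fit that left out 1 library but that without dKO ventricle 3 (log2 -0.22 to -0.18).

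**Figure D4:**
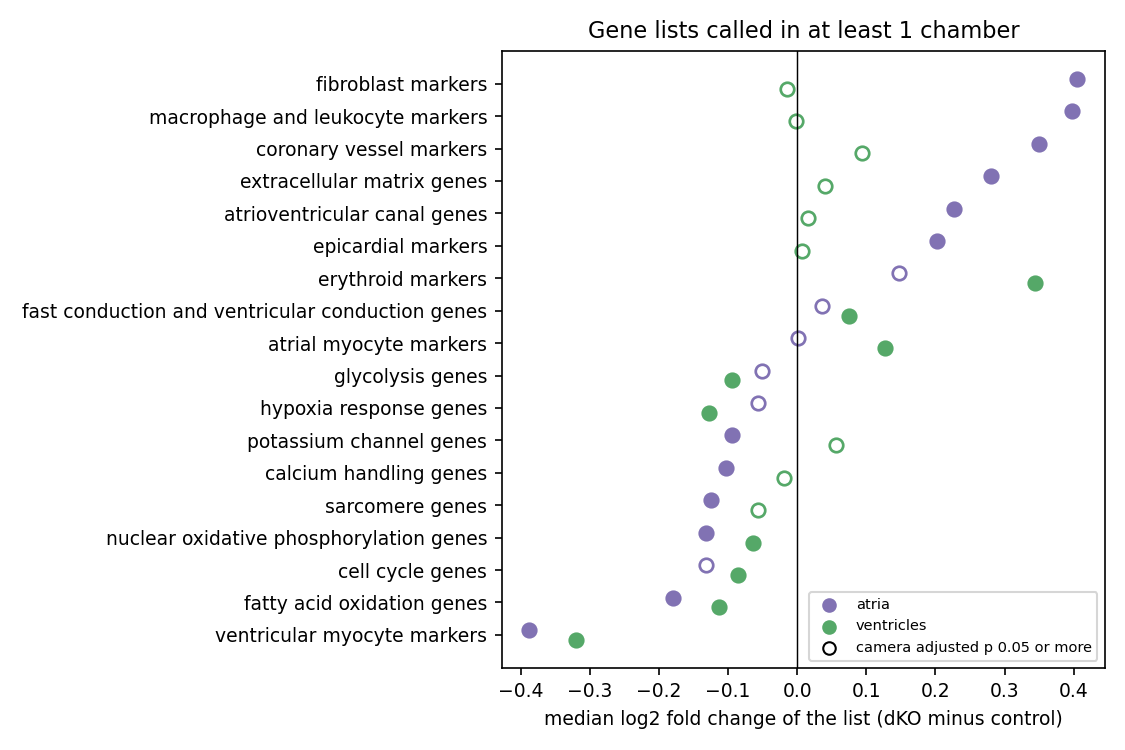
Median log2 fold change (x axis, dKO minus control) of each gene list called with camera in at least 1 chamber (y axis). Filled points passed a camera adjusted p of 0.05 at the preset correlation and open points did not, and ventricular myocyte markers lie lowest, at -0.39 in atria and -0.32 in ventricles.

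Some genes changed the same way in both chambers and others did not. The 8 shared genes with the smallest larger adjusted p were Sfrp5, Cdhr1, the Nogo receptor partner Lingo1 (log2 1.45 in atria and 1.08 in ventricles), the Wnt receptor Fzd1 (0.78 and 0.81), Ripor2 (1.40 and 0.69) and the noncoding Gm15487 (0.84 and 0.85), which rose, and Efnb3 (-2.09 and -0.78) and the glycogen primer Gyg (-1.24 and -0.48), which fell. Under the non-myocyte covariate Cdhr1 and Gm15487 (0.54) lost their calls in atria. Of the called genes 133 were called in both chambers, against 20.8 for independent lists, with 67 higher in both (5.57 for independent lists), 61 lower in both (4.84) and 5 in opposite directions. Both chambers come from the same embryos, so embryo differences add to this overlap. Across the 13950 genes the fold changes of both chambers had a Pearson correlation of 0.393 and a Spearman correlation of 0.310, and genes are not independent replicates. Of the 35 splits of the embryos into 4 and 4, 10 gave a correlation as high.

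The dKO effect itself differed between chambers for 350 genes, 177 more positive and 173 more negative in ventricles, by the limma test of the difference with embryo as a block. EdgeR called 307 and DESeq2 396. Among the more positive differences were those of Uts2b (log2 3.16), Ap3b2 (2.74), Dsc2 (2.12), Cckar (2.12) and Dpp6 (2.07), which fell in dKO atria. The call of this difference was lost by edgeR for Uts2b, Ap3b2, Cckar and Dpp6, by DESeq2 for Uts2b, Cckar and Dpp6, and on undamped log2 values for Cckar and Dpp6 (adjusted p 0.0529 to 0.273). Over the alternatives it measured 1.75 to 5.16 for Uts2b, 1.55 to 3.73 for Ap3b2, 0.90 to 4.26 for Cckar and 1.18 to 2.28 for Dpp6. Uts2b measured 0.0634 and 0.0492 CPM, Ap3b2 0.188 and 0.181 CPM and Ces1d 0.0656 and 0.161 CPM in dKO and control ventricles, at or near the floor of 3 reads, so no fold is given there. Dsc2 measured 36.3 CPM in both ventricular groups. Among the more negative differences were those of Adra1d (-2.12), Ces1d (-2.02), the cartilage collagen Col2a1 (-1.92), Ssc5d (-1.76) and the matrix proteoglycan Spock2 (-1.43). That of Ces1d, which rose in dKO atria, lost its call by edgeR, by DESeq2 and on undamped log2 values (adjusted p 0.140 to 0.351) and measured -4.30 to -1.06 over the alternatives. Adra1d rose in dKO atria (1.16) and fell in dKO ventricles (-0.96), while Col2a1 (1.20) and Spock2 (1.05) rose in dKO atria and measured -0.72 and -0.38 in ventricles, below the threshold. The effect also differed for Nppa (1.26, adjusted p = 0.00312) and Myom2 (1.58, adjusted p = 1.16e-06), higher in ventricles, and for Gja1 (1.06, adjusted p = 0.000126), which fell further in atria. The count of 350 was 230 without control embryo 1 and 222 without control embryo 4.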

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

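The tests of a wrong genotype label and of a lower share of myocytes below were chosen or changed only after the result was seen, and the covariate of cells other than myocytes was chosen after seeing the data.

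Meis1 was lower in dKO atria alone and Meis2 in dKO ventricles alone. Against a wrong genotype label of single libraries stands their placement by the genes called between the other 7 libraries of their chamber. With Meis1 and Meis2 left out, 16 of 16 libraries were placed with their own genotype. Labels exchanged for all libraries, or a genotype other than the stated one, would pass this test as well. The title number is argued against as the whole cause. With it as a covariate Meis1 in atria kept a log2 difference of -0.58 (limma adjusted p = 0.000707) and Meis2 in ventricles -0.77 (adjusted p = 0.000585). In these fits the covariate absorbs dKO embryo 1, whose title number covers no other embryo. A candidate explanation that stays open is that more cells other than myocytes, which keep both genes, hide a fall of Meis2 in dKO atria. With the mean level of 5 lists of such cells as a covariate Meis2 in atria measured -0.067 ± 0.18 SE, and the bound that would exclude it, -0.36, lies within 2 SE, while Meis1 in atria measured -0.65 ± 0.206 SE against -0.62 ± 0.0871 SE without it and lost its call (limma adjusted p = 0.190), as its SE grew. This candidate covers Meis2 in atria and not Meis1 in ventricles. There the mean level of these lists overlapped, at 4.95 to 5.10 in dKO and 5.01 to 5.12 in control ventricles. A different need for either gene in each chamber, or transcripts that lack the deleted exons, was not tested.

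By camera at the preset correlation, 12 lists were called in dKO atria, among them 4 of cells other than myocytes that were higher and metabolic and sarcomere lists that were lower, while with an estimated correlation 0 were called (3 with fry, and 20 at an unadjusted p under 0.05 with the preset correlation). Those called with fry were ventricular markers, potassium channels and BMP and TGF-beta genes, the last not among the 12. The title number is argued against as the whole cause. With it as a covariate 11 of the 12 called lists, all but potassium channels, kept direction and call. The title number of dKO embryo 1 covers no other embryo, so the covariate absorbs that library and the kept calls rest on the others. After re-centring 12 of 12 kept both. Re-centring moves all genes of a library alike and camera compares a list with the other genes, so this decides little about the scaling. With quantile normalization the sarcomere list lost its call and the other called lists kept theirs. A lower share of myocytes, with every other cell type raised alike, was weighed and stays undecided. The mean level of atrial myocyte markers, which such a share would lower, differed by a log2 of 0.014 (exact permutation p = 0.829). That of sarcomere genes was lower in dKO atria (log2 -0.16, exact permutation p = 0.0857). In dKO atrium 1 epicardial and endothelial markers lay above every control, while fibroblast and macrophage markers lay inside the control range. The difference between the fibroblast and endothelial list means was higher in dKO atria by a log2 of 0.22 (SD 0.415 and 0.161, two-sided exact permutation p = 0.371), and a p of this size shows no equality, so the reading first planned for it, that lists which are not told apart fit this explanation, was dropped and nothing is decided. Chance is not excluded for the number of lists either, and a change of state within myocytes or fibroblasts stays open as untested.

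Single libraries stood apart from the other 3 of their group where the gap to the nearest value exceeded 0.829 of the range (Dixon). Among 532 groups of 4 values, from 133 genes, 33 did so, where chance gives about 26.6, and no cause was sought. Control atrium 1 had Cd34 (32.7 CPM against 42.2 to 44.1, ratio 0.832) and Togaram2 (0.219 CPM against 0.640 to 0.687, ratio 0.900). In control atrium 2 this held for Fzd1 (67.1 CPM against 60.9 to 61.9, ratio 0.839). Control atrium 3 had Camk2a (105 CPM against 120.5 to 123, ratio 0.855), Gsg1l (41.2 CPM against 57.6 to 60.6, ratio 0.847), Ldb3 (703 CPM against 667 to 672, ratio 0.864) and Xirp2 (4.40 CPM against 6.28 to 6.53, ratio 0.883). In control atrium 4 this held for Fabp4 (16.9 CPM against 20.8 to 21.4, ratio 0.863) and P4ha1 (65.3 CPM against 84.4 to 86.9, ratio 0.884). Control ventricle 1 had Dcn (134 CPM against 115 to 117, ratio 0.917), Msln (18.1 CPM against 11.9 to 12.55, ratio 0.892) and Tcf21 (32.7 CPM against 19.5 to 21.4, ratio 0.852). In control ventricle 2 this held for Alox5 (6.29 CPM against 4.73 to 4.93, ratio 0.875) and Uts2b (0.132 CPM against 0.0183 to 0.0238, ratio 0.951). Control ventricle 3 had Fbn1 (211 CPM against 199.9 to 201, ratio 0.911) and Lingo1 (4.88 CPM against 5.76 to 5.87, ratio 0.885). In control ventricle 4 this held for Cenpa (95.5 CPM against 87.8 to 89.1, ratio 0.842). Library dKO atrium 1 had Acadl (349 CPM against 303 to 309.8, ratio 0.857) and Myl3 (59.1 CPM against 31.3 to 34.3, ratio 0.892). In dKO atrium 3 this held for Eprn (0.339 CPM against 0.101 to 0.136, ratio 0.854) and Tnni2 (8.35 CPM against 4.83 to 5.08, ratio 0.928). Library dKO atrium 4 had Fzd1 (101 CPM against 110.0 to 111, ratio 0.874), Hmga1 (39.1 CPM against 13.1 to 13.3, ratio 0.991) and Ripor2 (16 CPM against 26.8 to 28.2, ratio 0.882). In dKO ventricle 1 this held for Abcc9 (155 CPM against 133 to 136, ratio 0.871). Library dKO ventricle 2 had Acads (107 CPM against 91.4 to 93.9, ratio 0.841), Bmp5 (20.0 CPM against 23.9 to 24.5, ratio 0.863), Cacna1h (98.7 CPM against 114 to 115, ratio 0.912) and Eci1 (101 CPM against 84.5 to 85.8, ratio 0.923). In dKO ventricle 4 this held for Cpne5 (2.83 CPM against 6.49 to 7.20, ratio 0.837), Hmga1 (49.96 CPM against 25.9 to 27.9, ratio 0.918), Ryr3 (4.36 CPM against 3.07 to 3.18, ratio 0.911) and Spock2 (10.4 CPM against 7.32 to 7.64, ratio 0.898). Hmga1 thus stood apart in both chambers of dKO embryo 4.

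The dKO effect differed between chambers, by the test of the difference (limma adjusted p under 0.05), in 57 of the 133 genes, 37 more positive and 20 more negative in ventricles minus atria. Most of these genes were named for calls in the same data, some by this very test, so their share and balance are no result. Over all 13950 genes tested 350 differed, 177 more positive and 173 more negative. The larger log2 differences were Uts2b 3.16, Ap3b2 2.74, Dsc2 2.12, Cckar 2.12, Dpp6 2.07, Ryr3 2.06, Gsg1l 1.91, Lrrc10 1.73, Myom2 1.58, Myl3 1.57, Nsg2 1.42, Dgkk 1.38, Xirp2 1.33, Efnb3 1.31, Nppa 1.26, Cited1 1.21, Tmeff2 1.12, Gja1 1.06 and Abcc8 1.003. The smaller ones were Etv1 0.94, Bmp5 0.92, Abcc9 0.84, Slit3 0.80, Hspb7 0.77, Gyg 0.76, Kcnq1 0.63, Sema6d 0.63, Meis1 0.60, Epha4 0.58, Kcnj5 0.58, Fabp3 0.49, Wnt5a 0.46, Tbx20 0.46, Cacna1c 0.45, Hspb1 0.42, Camk2a 0.41 and Hk1 0.39. In the other direction the values were Adra1d -2.12, Ces1d -2.02, Col2a1 -1.92, Ssc5d -1.76, Spock2 -1.43, Slco5a1 -1.37, Cspg4 -1.36, Csrp2 -1.25, Gad1 -1.19, Dio2 -1.14, Tnni2 -1.05, Meis2 -0.79, Acta2 -0.74, Ripor2 -0.71, Clu -0.69, Rcan1 -0.57, Sfrp1 -0.52, Cd34 -0.48, Smad7 -0.47 and Smoc2 -0.42.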

How the results depend on the processing

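The edgeR, DESeq2, undamped log2, at least 5 CPM, non-myocyte covariate and thinned-read settings were chosen after seeing the data. Counts not given below moved by no more than 1.5 times. Of the 4055 values of named genes under alternatives, 3748 counted as unchanged, 300 lost the call, 1 gained it and 6 reversed. A reversal was counted only for genes called in the main fit. Genes not called there counted as unchanged when their sign turned, as for Meis1 in ventricles (-0.082 to 0.027) and Meis2 in atria (-0.067 to 0.106). With a mean of at least 50 CPM, which tests 3622 genes, the counts were 422 in atria, 135 in ventricles, 148 for the difference between chambers and 2271 for the chambers of controls, and with a fold of at least 2 they were 115, 25, 84 and 900. The title number shared by 2 embryos of each genotype, taken alone, gave 944 atrial and 79 ventricular genes, of which 61 were among the 279. DESeq2 gave 1552, 469, 396 and 5700. The cause was not tested. The non-myocyte covariate gave 163 genes in atria, 98 of them among the 1042, and 284 in ventricles, and it goes with the groups in atria. Under it Abcc8 (0.033), C1qb (-0.13), Fabp4 (-0.37), P4ha1 (-0.063), Tbx2 (-0.035) and Tcf21 (-0.21) reversed in atria, all with adjusted p of 0.346 or more; the cause was not tested. Lists called in atria went from 12 to 6 at 50 CPM, 0 with an estimated correlation and 3 with fry, and in ventricles from 9 to 0 with an estimated correlation and 1 with fry. At an unadjusted p under 0.05 with the preset correlation there were 20 and 12. The 3 atrial lists of fry were ventricular markers, potassium channels and BMP and TGF-beta genes, the last not among the 12. The correlation of fold changes was 0.549 at 50 CPM, 0.473 at 5 CPM and 0.548 over called genes. Leaving out 1 embryo gave correlations of 0.337 (without dKO embryo 1) to 0.433 (without control embryo 1) and counts of 222 to 445 for the difference between chambers, with 230 without control embryo 1 and 222 without control embryo 4. Leaving out 1 library gave 695 to 1201 atrial and 187 to 261 ventricular genes. The embryo as a random block gave 1459 and 264 genes and no replicate block 294 for the difference between chambers; the block moved no count by more than 1.5 times. Ventricular reads thinned to the shallowest library gave 220 genes, 209 of them among the 279. Under the pseudocounts, re-centring and leaving out 1 library, Meis1 in atria (log2 -0.69 to -0.55) and Meis2 in ventricles (-0.79 to -0.64) kept their direction and an exact permutation p of 0.0286. The covariate for Y-linked genes was not run, because all 8 embryos express Y-linked genes. Depth limits genes near the floor of 0.110 to 0.312 CPM.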

Other observations

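The tests of chance, of the title number and of developmental stage below were set before their values were seen, and the test of depth, the covariate of cells other than myocytes, edgeR and thinned reads after the data were seen.

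Signalling and guidance genes moved both ways in dKO atria. Of 20 BMP and TGF-beta genes 4 rose and 2 fell (camera adjusted p = 0.0519, fry adjusted p = 0.0490), with rises of the ligand Bmp2 (log2 0.73) and the inhibitor Smad7 (0.40) and a fall of the ligand Bmp5 (-0.87). Of 16 Wnt genes 2 rose and 4 fell (camera adjusted p = 0.496), with a rise of the secreted antagonist Sfrp1 (0.90) and falls of Wnt5a (-0.62) and Dkk3 (-0.78). Of 24 semaphorin, ephrin and Slit genes 3 rose and 2 fell (camera adjusted p = 0.0804), with falls of the guidance cue Slit3 (-0.71) and of Sema6d (-0.77) and rises of Efnb1 (0.31) and Sema3a (0.56). In the Notch list Hey1 (-0.60) and Dll1 (-0.44) fell among 15 (camera adjusted p = 0.648). In ventricles Sfrp1 rose (0.39) among 16 Wnt genes, Epha4 rose (0.55) and Sema3c fell (-0.59) among 24 guidance genes, and Id2 fell (-0.42) among 20 BMP and TGF-beta genes. Of the fits that left out 1 library, Dll1 lost its call in all but that without dKO atrium 4 (-0.48 to -0.33), Epha4 in all but those without dKO ventricle 2 or control ventricle 4 (0.46 to 0.58), Sema3c in all but that without dKO ventricle 4 (-0.65 to -0.49), and Sfrp1 in ventricles without dKO ventricle 3 or control ventricle 1, 2 or 4 (0.35 to 0.39). With no filter Dll1, Epha4, Sema3c and Sfrp1 in ventricles lost theirs (adjusted p of at most 0.0856), by edgeR Dll1 and Sema3c (0.0536 and 0.0552), with the title number as a covariate Dll1 (0.0572), and after re-centring or with thinned reads Sema3c (0.0512 and 0.0511). Within the 4 embryos of the balanced number, described below, Dll1 and Hey1 in atria and Epha4, Sema3c, Sfrp1 and Id2 in ventricles lost theirs (0.0550 to 0.383). With the mean level of 5 lists of cells other than myocytes as a covariate, Bmp2 (0.81), Smad7 (0.43), Bmp5 (-0.51), Wnt5a (-0.33), Dkk3 (-0.53), Sema6d (-0.37), Efnb1 (0.30), Sema3a (0.95), Hey1 (-0.84) and Dll1 (-0.41) lost theirs in atria (adjusted p 0.0685 to 0.596).

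Stress and early response genes also moved both ways in dKO atria. Of 16 immediate early genes Egr1 (0.66) and Klf4 (0.40) rose and Ier3 fell (-0.99; camera adjusted p = 0.339), of 14 heat shock genes Hspb1 fell (-0.42; camera adjusted p = 0.348), and of 18 hypoxia genes P4ha1 rose (0.37) while Slc2a1 and Adm fell (camera adjusted p = 0.0804). The mean level of the heat shock list was higher in dKO atria despite the fall of Hspb1 (log2 0.08, exact permutation p = 0.0286, fry adjusted p = 0.0997). The pacemaker list member Smoc2 (0.52) and the skeletal troponin Tnni2 (1.10) rose, and the transcription factor Mef2d fell (-0.23). No p53 target of 16 was called by limma in either chamber (0 in atria and 0 in ventricles). The mean level of the p53 list was higher in dKO atria (log2 0.06, exact permutation p = 0.0286, camera adjusted p = 0.396). The exact p of list means are not adjusted over the lists. Of the fits that left out 1 library, Klf4 lost its call in all but those without control atrium 1 or 4 or dKO atrium 4 (0.34 to 0.42), Mef2d in all but those without dKO atrium 1 or 4 or control atrium 3 (-0.23 to -0.21), P4ha1 in all but those without dKO atrium 1 or control atrium 1 (0.28 to 0.41), and Smoc2 without control atrium 4 (0.47). Klf4 also lost it with the title number as a covariate (adjusted p = 0.0648), P4ha1 with no filter (0.0561), and Klf4, Smoc2 and Adm within the 4 embryos of the balanced number (0.101 to 0.187). With the covariate of cells other than myocytes Egr1 (0.64), Klf4 (0.73), Ier3 (-1.13), Hspb1 (-0.52), Smoc2 (0.35), Tnni2 (0.83), Mef2d (-0.05), Slc2a1 and Adm lost theirs (adjusted p 0.0905 to 0.897), and P4ha1 turned to -0.063.

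The 3 numbers in the sample titles, whose meaning the labels do not state, group the embryos as 1 dKO embryo, 2 embryos of each genotype (the balanced number), and 2 control and 1 dKO embryo. With genotype as a covariate, 17 genes differed between the 4 ventricles of the balanced number and the other 4, 7 of them higher in the former, and 8 genes differed in atria. Myh6, the alpha-myosin heavy chain, measured 1615 to 1869 CPM in ventricles of the balanced number and 3322 to 4432 CPM in the others (log2 -1.20, exact permutation p = 0.0286), and Eln, elastin, averaged 136 against 384 CPM, Fbln5 20.7 against 49.0, Rplp0 669 against 1041, Gm3375 0.0326 against 24.2 and Gm15920 10.7 against 0.0530. Depth is argued against as the whole cause, since 3 of the 4 ventricular libraries of the balanced number lay inside the range of reads of the others, and a litter, a day of collection or a strain background behind the numbers was not tested. A difference of developmental stage may account for it and stays open, since the cell cycle list mean differed by 0.05 (exact permutation p = 0.4) and the fatty acid oxidation list mean by 0.08 (exact permutation p = 0.286), which decides neither way, although the reading first planned took such a p as evidence against it.

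Chance is argued against, but not excluded, for the number of called genes. Of the 35 splits of the 8 embryos into 4 and 4, only the real split, 1 of 35, gave 1042 genes in atria (highest other 6), 279 in ventricles (highest other 8) and 350 for the difference between chambers (highest other 0). This share, 0.0286, is the smallest that 35 splits allow. Every other split mixes both genotypes within its groups, so a genotype difference widens their spread and lowers their counts. The highest other split in atria and in ventricles was that of the balanced number against the others, and within that number the comparison called 944 and 79 genes. Chance is not excluded for the lists, as 11 of 35 splits called as many lists as the 12 in atria (highest other 18) and 13 as many as the 9 in ventricles (highest other 13, and 12 for the split by the balanced number). Nor is it excluded for the correlation of 0.393 between chambers, since 10 of the 35 splits gave as high a value and the split by the balanced number gave the highest, 0.494. For the chambers of control embryos, the 8 swaps of chambers are too few for a share under 0.05; the real labels, 1 of 8, gave 6401 genes and the highest other swap 0.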
